A study of Mus musculus with 2 samples.

How the data were processed

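Single-nucleus RNA was measured in nuclei of tumour-associated macrophages (TAMs) from mammary tumours of PyMT mice, which carry the polyoma middle T oncogene, on a low protein diet. There were 2 samples, 1 per genotype: control-PyMT, and MYC-PyMT with S100a8-cre and a cre-dependent MYC allele. Per the labels' protocols, recipients were irradiated at 7 weeks of age and given bone marrow of Fcgr1-cre mice with a cre-dependent H2B-mCherry allele, so that nuclei of cells with a history of Fcgr1 expression fluoresce. The diet began 2 weeks later and lasted 6 weeks. TAMs were sorted as living CD45, F4/80 and Vcam positive cells negative for Siglec-F, Ly6G, B220 and Ly6C. Their nuclei were sorted again as mCherry and SYTO9 (a nucleic acid dye) positive and CD11b negative. Libraries were made with the 10x Genomics 3' v3 kit, with 11 cycles of cDNA amplification.

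The authors deposited a matrix of unique molecular identifier (UMI) counts per gene and barcode, with a list of 32285 genes and a list of 1838 barcodes. Each count is a number of distinct molecules, so that PCR copies do not add to it. Reads were processed with Cell Ranger 5.0 on mouse build mm10, per the submitters' processing notes, and the matrix gives software version 5.0.1, per the file headers. The gene annotation, whether intronic reads were counted, how barcodes were called as nuclei and whether depth was equalised between libraries are not given in the sources used here. In nuclei, most transcripts are unspliced, so the counting of introns would change the level of long genes. Of the gene identifiers, 32158 were found in the GENCODE vM21 annotation of GRCm38, the assembly named mm10, and gene positions come from there. The symbol Mx1 was missing from the gene list. No feature stood for mCherry or cre. Antibodies to B220 and CD45 bind products of the same gene, Ptprc, which counts at the 3' end cannot tell apart.

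Barcodes carry the suffix 1 or 2, which marks 2 wells. No label ties a suffix to a genotype, so 0 of the 2 wells could be mapped, and the matrix was treated as 1 pooled sample. No genotype comparison, p-value, standard error or count of changed genes was made. Values per well are given as those of an unmapped well. Tests that use them are in the closing section and concern explanations of patterns, not a difference between genotypes. Intervals are exact 95% intervals, Poisson for summed counts, conditional binomial for ratios of counts and Clopper-Pearson for shares of nuclei. They cover counting error only, not differences between mice or libraries.

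Nuclei with under 500 UMIs (11 barcodes), under 300 genes (5) or over 5% of UMIs from mitochondrially encoded genes (9) were removed, 21 in all. Scrublet, run per well in scanpy 1.11.5, called 0 doublets in well 1 and 5 in well 2 (1.14%), which were also removed. This yield is low and doublets of like nuclei would remain. The 1812 nuclei kept held 7342649 UMIs. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were ranked by a Seurat v3-type standardised variance written for this work (lowess fit from statsmodels 0.14.6 with a span of 0.3), and 30 principal components and 15 neighbours entered Leiden clustering at resolution 0.5 (igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Figures were drawn with matplotlib 3.10.9.

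Clusters were numbered by size and named by markers of 12 cell types. A marker counted for a cluster with at least 5 UMIs, 20 CPM (UMI counts scaled to a common library total) and 0.5 of its highest cluster level there, and at least 3 markers were needed. A cluster stayed unnamed where its 10 leading genes by fold (each with at least 10 UMIs and 50 CPM) held more markers of another type or 3 or more mitochondrially encoded genes. It also stayed unnamed where its median UMI count was low with none of its markers leading. The markers, gene lists, filters and the rule for named genes were fixed before the data were examined. The scoring and the minimums for leading genes were set after clusters had been seen: a minimum of 30 UMIs, used at first, would have named cluster 2 macrophage-like as well. The design allowed more than 1 ranking of variable genes. The 3 rankings tried were viewed in 14 clusterings of all nuclei and 4 of phagocyte nuclei. A ranking by Pearson residuals was for a time taken as the main one because its clusters looked cleaner, and so was a set that included cluster 2. Both choices followed the results and were undone: the ranking named first in the design and the named clusters alone give the main results. The wider set is reported as an alternative chosen after seeing the data.

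Levels are CPM of counts summed over nuclei. Macrophage-like nuclei were clustered again on a random 0.5 share of each nucleus's counts, and levels per sub-cluster were measured on the remaining counts, so that the noise that shaped a sub-cluster does not enter its levels. The choice of the nuclei themselves used all counts. A list was called higher in a sub-cluster at 1.5-fold or more of its level in all other nuclei of the set, with a 95% interval above 1. There were 21 functional lists: the markers the gate selects for, those it selects against, TAM, mammary tissue-resident macrophage, lipid-associated macrophage, the FLCN-Rag-TFE pathway, lysosome, mTORC1 and amino-acid sensing, the ATF4 amino-acid response, amino-acid transport, phagocytosis of dying cells, MHC class II, interferon, NF-kB, alternative activation, hypoxia and glycolysis, S phase, G2 and M phase, ribosome biogenesis with Myc, immediate early and heat shock genes, and receptors. Within-well ratios were computed where each side held at least 20 nuclei of the well. Shares of nuclei with a UMI were compared after thinning each nucleus to 1000 UMIs.

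The rule for named genes took the gate genes with Myc, S100a8 and Fcgr1, the 3 highest members of each list, and, for each sub-cluster, the 6 genes with the highest ratio among those with at least 30 UMIs and an interval above 1.5-fold. For other clusters it took the 5 genes with the highest ratio, and 6 for clusters 1 and 3, under the same minimums on all counts. Mitochondrially encoded, ribosomal protein and predicted genes were left out of these rankings, though not of the leading genes used for naming. List members beyond these are named where a list's call rests on them, and were chosen after their values were seen. On data simulated from the summed profile over all 32285 genes, 44 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were called above 1.5-fold, against 0 of 2848 unchanged genes. The changed nuclei there were a known 1 in 3, without clustering, with counting noise alone and genes of at least 30 expected UMIs. Sub-clusters of few nuclei and noise beyond counting are not covered. In simulated homogeneous nuclei, clustering and measuring on separate counts gave 1 gene call and 0 list calls. The ordering of nuclei by lysosome level gave 1 list call with a ratio of up to 1.77 where none was simulated. Alternatives changed the filters, the doublet step, the resolution, the number of variable genes, the seed, the scaling, the limits, the ranking, the naming minimum, the set of nuclei and the wells used. The values of some genes are not reported here.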

Results

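The matrix held 7381447 UMIs over barcodes of 2 wells. Well 1 had 1383 barcodes with 5868606 UMIs and a median of 2487 per barcode, and well 2 had 455 barcodes with 1512841 UMIs and a median of 2834. After filtering, 1377 nuclei of well 1 and 435 of well 2 remained. The study set TAM nuclei of MYC-PyMT mice beside those of control-PyMT mice on a low protein diet, with 1 sample per genotype. That comparison cannot be drawn from the matrix, because neither well carries the name of a sample. Myc itself had 98 UMIs over all nuclei (13.3 CPM, 95% interval 10.8 to 16.3), with 13.5 CPM in well 1 and 12.8 CPM in well 2. S100a8, a neutrophil gene whose promoter drives the cre of the MYC-PyMT mice, had 69 UMIs (9.40 CPM, 7.31 to 11.9), with 11.1 CPM (8.56 to 14.1) in well 1 and 2.69 CPM (0.734 to 6.90) in well 2. Of these UMIs, 34 were in clusters 5 and 6, which had epithelial markers, and 6 in macrophage-like nuclei, both described below. In the low-UMI cluster 4, S100a8 and S100a9 were counted as neutrophil markers. The labels name no MYC allele in the marrow donors, so the level of neither gene in marrow-derived nuclei would check the genotype of a recipient, and levels over all nuclei mix these with other nuclei.

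Transcripts of the surface proteins used in the sort were abundant, and those of most excluded lineages were close to absent. Ptprc, which encodes CD45, stood at 639 CPM over all nuclei (95% interval 621 to 658). Adgre1, which encodes F4/80, stood at 267 CPM (256 to 279), Vcam1 at 108 CPM (100.7 to 116) and Fcgr1, the high-affinity IgG receptor gene whose promoter drives the cre of the donors, at 33.6 CPM (29.6 to 38.1). The 4 genes together reached 1942 CPM (1890 to 1996) in the macrophage-like nuclei described next, against 26.4 CPM (21.0 to 32.8) in clusters 5 and 6, which had epithelial markers counted and no macrophage ones. Adgre1 and Fcgr1 are also among the markers that named the clusters, so the naming set part of this contrast and of their shares below. Of genes selected against, Siglecf had 2 UMIs in all nuclei, Ly6c1 had 2, Ly6c2 had 2 and Ms4a1 had 5. Ly6g had 0 UMIs in 1812 nuclei, which allows a share of up to 0.166% of nuclei with a UMI (3 counts of the total; the exact 95% interval ends at 0.203%). Itgam, which encodes CD11b, was the exception with 912 UMIs (124 CPM, 116 to 133). The nuclear sort used CD11b to leave out whole cells, so its transcript need not follow the sort. After thinning to 1000 UMIs, Adgre1 was seen in 33.6% of macrophage-like nuclei (30.3 to 37.0), Vcam1 in 16% (13.6 to 18.8) and Fcgr1 in 5.60% (4.11 to 7.42). In nuclei of clusters 5 and 6 the shares were 2.02%, 0.405% and 0%. Before thinning, the macrophage-like shares were 59.0%, 30.7% and 15.2% at a median of 2754 UMIs, and those of clusters 5 and 6 were 5.26%, 2.26% and 2.26% at a median of 5281 UMIs. On mouse build GRCm38, Ptprc lies at chromosome 1, 138062861 to 138175708, Adgre1 at chromosome 17, 57358691 to 57483527, Vcam1 at chromosome 3, 116109949 to 116129688, Fcgr1 at chromosome 3, 96282909 to 96293969, and Itgam at chromosome 7, 128062640 to 128118491.

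Nuclei fell into 7 clusters, and the 3 that held most of them had macrophage markers counted and no epithelial ones. Clusters 1 (557 nuclei) and 3 (16.7% of nuclei) were macrophage-like, each with 8 of 11 macrophage markers counted, among them Adgre1, Csf1r (the receptor for macrophage colony-stimulating factor), Mertk, a receptor for dying cells, and the complement genes C1qa, C1qb and C1qc. Together they made up 860 of 1812 nuclei, or 47.5% (95% interval 45.1 to 49.8). Cluster 1 was led by Trim55, Sycp2, Asb2, Lpar3, Minar1 and Scimp, and cluster 3 by Hdc, Tspoap1, Pde4c, Arl5c, Clec1a and Nlrp3. The Hdc level of cluster 3 came largely from 5 of its nuclei, described below as sub-cluster 4. Nlrp3, the inflammasome sensor, reached 616 CPM in cluster 3, and the cytokine gene Il1b was also among its leading genes. Cluster 2 (383 nuclei) had 10 of 11 macrophage markers counted, but also 4 monocyte markers (Ccr2, Vcan, F13a1 and Fn1), and stayed unnamed because the monocyte marker F13a1, and no macrophage marker, was among its 10 leading genes. Its highest ratios belonged to Lyve1, the hyaluronan receptor of some resident macrophages, at 74.9 CPM, Uty at 345 CPM, Retnla at 113 CPM, Ms4a8a at 93.9 CPM and Kdm5d at 41.0 CPM. Uty and Kdm5d are Y-linked. Itgam reached 429 CPM (394 to 467) in cluster 2 against 127 CPM (114 to 141) in macrophage-like nuclei, and Vcam1 67.0 CPM (53.6 to 82.9) against 253 CPM (234 to 273). Had cluster 2 been counted, the share would have been 68.6% (66.4 to 70.7), an alternative chosen after seeing the data.

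Outside these clusters, mammary epithelial genes were the most frequent. Cluster 5 (216 nuclei) had 7 of 10 epithelial markers counted, with Erg, Lama3, Fst and Pde3a among its genes of highest ratio, and stayed unnamed because the B cell marker Ebf1 was among its leading genes. Cluster 6 (50 nuclei) was epithelial-like with 6 of 10 markers and was led by Kcnj16, Tinag, Adcy8, Zfp385b and Tcfl5. Kcnj16 and Tinag had 30 UMIs each there. Depth was uneven, with a median of 4899 UMIs and a highest of 103328 in cluster 5. In cluster 6 these were 8470 and 97412. A few deep nuclei can thus weigh on the summed levels of both clusters. Epcam reached 447 CPM and Krt8 497 CPM in clusters 5 and 6 together, against 41.4 CPM and 58.3 CPM in macrophage-like nuclei. Cluster 4 (292 nuclei) had a median of 692.5 UMIs and markers of both kinds, 7 of 10 epithelial (14242 CPM summed, against 10177 CPM in cluster 5 and 11289 CPM in cluster 6) and 5 of 11 macrophage (5775 CPM, against 5672 CPM in cluster 1 and 5685 CPM in cluster 3). Neutrophil (S100a8 and S100a9), fibroblast (Col1a1 and Col1a2), mast cell (Kit) and endothelial (Flt1) markers were counted there as well. Cluster 4 stayed unnamed because mitochondrially encoded genes were among its leading genes. Among named nuclear-encoded genes with at least 30 UMIs, leaving out predicted genes and those of ribosomal proteins, its highest ratios were those of Rgs5, Gjb2, Wfdc18 (a milk whey protein gene), Snrpd2 and Uqcr10. Ribosomal protein genes took 64545 CPM in cluster 4 against 10164 CPM in cluster 1 and 8779 CPM in cluster 3, and mitochondrially encoded genes 11632 CPM against 627 CPM and 487 CPM. Cluster 7 (11 nuclei) was T cell-like on 3 of 8 markers, Lck and Skap1 among them, and was led by Il2rb, Skap1, Clnk, Tox and Dscam, with 2 markers of NK cells also counted.

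The 2 wells were filled by different clusters. In well 1, 61.0% of nuclei (95% interval 58.4 to 63.6) were in macrophage-like clusters 1 and 3 and 1.53% (0.946 to 2.32) in cluster 2. In well 2, 4.60% (2.83 to 7.01) were in clusters 1 and 3 and 83.2% (79.4 to 86.6) in cluster 2. With cluster 2 counted, the shares were 62.5% (59.9 to 65.1) in well 1 and 87.8% (84.4 to 90.7) in well 2. Clusters 5 and 6, with epithelial and no macrophage markers counted, held 17.1% of well 1 (15.2 to 19.2) and 6.90% of well 2 (4.70 to 9.70), and the low-UMI cluster 4, with markers of both kinds, held 19.6% and 5.06%. These are shares among sorted nuclei in 1 library each, with no replicate, and a cluster held mostly by 1 well may be that library rather than a cell type. Clustered alone, an alternative chosen after seeing the data, well 1 gave a macrophage-like share of 60.4% and well 2 one of 60%.

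**Figure D1:**
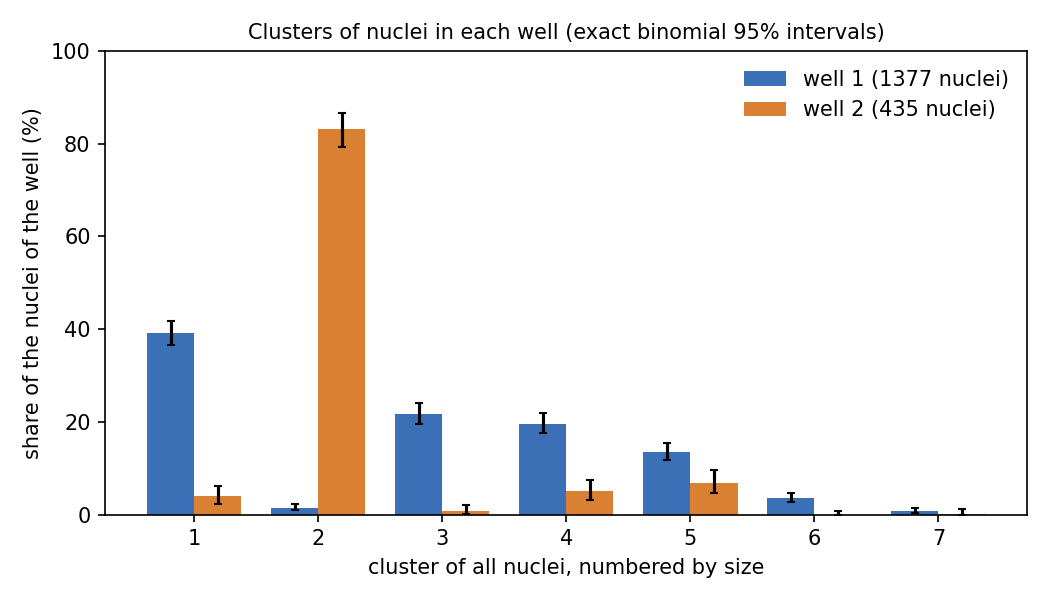
Share of the nuclei of each well (y axis, percent) in the 7 clusters of all nuclei (x axis, numbered by size). Bars are the 1377 nuclei of well 1 and the 435 of well 2 and error bars are exact binomial 95% intervals. Cluster 2 holds 83.2% of well 2 and 1.53% of well 1.

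Of the 21 lists, those of lysosomal, phagocytic and antigen presentation genes had the highest sums in macrophage-like nuclei. A sum grows with the number of members, so it does not rank programmes. In that order, the lists summed to 2832, 2441 and 321 CPM in cluster 5 and 3382, 2932 and 185 CPM in cluster 6. They were at 10608, 3705 and 7172 CPM in low-UMI cluster 4 and 2100, 6127 and 516 CPM in T cell-like cluster 7. The values that follow are those of macrophage-like nuclei. The lysosome list summed to 10762 CPM (95% interval 10638 to 10888), with 26 of 28 members at 10 CPM or more, led by Psap (1874 CPM), Lgmn and Ctsb, genes of a sphingolipid activator and of lysosomal proteases. Phagocytosis of dying cells summed to 8531 CPM (8421 to 8643; 16 of 19 members), led by Elmo1 (2989 CPM), Dock2 and Itgav, and MHC class II antigen presentation to 8396 CPM (8286 to 8506; 9 of 9), led by Cd74 (2272 CPM), Cd86 and H2-Eb1. Lipid-associated macrophage genes summed to 4952 CPM (4868 to 5038; 16 of 18), led by Apoe (1564 CPM), Abca1 and Lgals3. The TAM list summed to 1746 CPM (1696 to 1797; 7 of 8), led by the elastase gene Mmp12 (461 CPM), the fractalkine receptor gene Cx3cr1 and Mmp14. The tissue-resident list was far lower at 238 CPM (220 to 257), with 2 of 8 members at 10 CPM, Mrc1 (119 CPM) and Maf. Its next member, Cd163, had 2 UMIs, and Cd209f, Cd209g, Lyve1 and Timd4 had 0. These levels are those of a set with 840 of its 860 nuclei from well 1. In cluster 2 the order was reversed, with the tissue-resident list at 2416 CPM (2331 to 2503) and the TAM list at 1176 CPM (1117 to 1237), and with cluster 2 added to the set they were at 942 CPM (911 to 972) and 1562 CPM (1523 to 1601). The TAM list was higher still in cluster 6, at 2047 CPM (1953 to 2143), and in cluster 4, at 2219 CPM (2059 to 2388). It was at 1189 CPM in cluster 5 and 275 CPM in cluster 7. The tissue-resident list was at 36.3 CPM in cluster 6 and 130 CPM in cluster 4. Neither this TAM level nor a TAM list above the resident list is thus particular to macrophage-like nuclei. The receptor list summed to 1934 CPM (1881 to 1987; 9 of 9), led by Csf1r (601 CPM), Itgb1 and Itga4.

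Genes of nutrient sensing and lysosomal control were measured at middle levels. The FLCN-Rag-TFE list, the folliculin complex and Rag GTPases that control the TFE transcription factors in response to amino acids, summed to 2454 CPM (95% interval 2395 to 2515; 13 of 16 members at 10 CPM), led by Fnip2 (702 CPM), Fnip1 and Mitf. Amino-acid transport summed to 2519 CPM (2459 to 2580; 18 of 18), led by Slc15a3 (383 CPM), Slc43a2 and Slc38a6, and mTORC1 and amino-acid sensing to 1682 CPM (1633 to 1732; 19 of 25), led by Rptor (440 CPM), Rheb and Deptor. The ATF4 response to amino-acid shortage was lower at 550 CPM (522 to 579; 10 of 20), led by Cebpb (156 CPM), Atf4 and Nars, and Chac1 and Phgdh had 0 UMIs. Immediate early and heat shock genes summed to 6210 CPM (6116 to 6306; 11 of 11), led by Hsp90aa1 (1789 CPM), Atf3 and Jun. Alternative activation summed to 4915 CPM (4832 to 5000; 9 of 13), of which Tgfbr1 made up 3141 CPM, ahead of Tgfbr2 and Havcr2, and the NF-kB list to 3403 CPM (3333 to 3473; 11 of 12), led by Nfkb1 (809 CPM), Il1b and Nfkbiz. The interferon list gave 1733 CPM (1684 to 1784; 17 of 17 in the matrix), led by Trim30a, Parp14 and Ifi204. Hypoxia and glycolysis gave 1186 CPM (1145 to 1228; 12 of 15), led by Pfkfb3, Hk2 and Pkm. Ribosome biogenesis gave 663 CPM (633 to 695; 13 of 14), led by Ncl, Wdr43 and Nop56. S phase genes gave 374 CPM (351 to 398; 8 of 14), led by Pola1, Atad2 and Hells, and G2 and M phase genes 315 CPM (294 to 337; 12 of 15), led by Mki67, Diaph3 and Top2a. The genes selected against summed to 128 CPM (115 to 143), nearly all of it Itgam. Over the lists, 236 of 291 genes reached 10 CPM, and the 19 alternatives run gave 234 to 242. Of other cell types, epithelial markers had 1959 CPM (1906 to 2013) in macrophage-like nuclei, of which Trps1, a transcription factor gene, made up 1177 CPM. Neutrophil markers had 109 CPM, monocyte markers 57.2 CPM, endothelial 26.7 CPM, dendritic cell 19.2 CPM, mast cell 18.4 CPM, T cell 13.2 CPM, B cell 10.2 CPM, fibroblast 6.02 CPM, NK cell 1.13 CPM and eosinophil 0.376 CPM.

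Macrophage-like nuclei split into 4 sub-clusters. Sub-cluster 2, with 282 of its 343 nuclei from cluster 3, carried higher levels of immediate early, heat shock and NF-kB genes. Nuclei were taken after living cells had been sorted, and no unsorted sample shows whether these genes were on before the sort. In sub-cluster 3 the ATF4, TAM, hypoxia and glycolysis, FLCN-Rag-TFE and interferon lists were higher, each on a minority of its members. These calls were not stable. With another seed of the clustering and count split, only the TAM list of these was called in any sub-cluster. With well 1 alone, an alternative chosen after seeing the data, only the ATF4 and TAM lists of these were. In sub-cluster 2 (343 nuclei, all from well 1), immediate early and heat shock genes were 8.89-fold (95% interval 8.36 to 9.46) the level of the other macrophage-like nuclei, with 11 of 11 members higher, such as Atf3 at 13-fold and Hsp90aa1 at 10.5-fold. NF-kB genes were 4.77-fold (4.45 to 5.11), with 11 of 12 members higher, Il1b at 12.9-fold and Tnfaip3 at 7.32-fold among them. Its leading genes were Osm (35.3-fold, 9.22 to 299.8), Hsph1 (23.0-fold), Mpp7 (22.2-fold), Nr4a3 (17.0-fold), Fhad1 (17.0-fold) and Fosb (16.4-fold). Amino-acid transport was 1.54-fold (1.44 to 1.65) there, with 6 of 18 members higher and 3 lower. Slc15a3, a lysosomal carrier of histidine and peptides, was 5.37-fold and Slc38a2 3.95-fold, while Slc7a7 was 0.468-fold. The MHC class II list was 1.54-fold (1.49 to 1.60), on 2 of 9 members, the costimulatory genes Cd86 (5.36-fold) and Cd40 (2.86-fold), with 2 lower. H2-Aa was at 1.01-fold (0.904 to 1.13) and the class II transactivator gene Ciita at 0.645-fold (0.520 to 0.795).

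Sub-cluster 3 (37 nuclei, 34 of them from well 1) was led by Slc7a11 (20.4-fold), the cystine transporter gene, Mmp12 (8.14-fold), the peroxiredoxin gene Prdx1 (6.19-fold), Alcam (6.09-fold), Cxcl2 (5.16-fold) and Tnf (5.01-fold). The ATF4 list was 2.87-fold (95% interval 2.27 to 3.59), on 4 of 18 measured members, Slc7a11, Sars, Cebpb and Atf4. The TAM list was 2.33-fold (2.02 to 2.68), on Mmp12 and Itgax, with Cx3cr1 at 0.126-fold (0.0259 to 0.370) and Vcam1 at 0.379-fold. Mmp12 made up 162 of the 219 UMIs of the list there, and the ratio without it was not computed. Hypoxia and glycolysis genes were 2.30-fold (1.93 to 2.72), with 6 of 15 members higher, among them Pgk1 (4.66-fold), Eno1 (4.56-fold) and Pkm (3.84-fold). FLCN-Rag-TFE genes were 2.20-fold (1.95 to 2.48), with 5 of 16 members higher, among them Fnip2 at 4.05-fold, Flcn at 3.21-fold, Fnip1 at 2.12-fold and Mitf at 1.52-fold, while Tfeb was 0.409-fold. The interferon list was 1.77-fold (1.51 to 2.07), with 4 of 17 members higher, Ifit2 (9.50-fold), Ifit1 (7.73-fold), Cxcl10 (6.95-fold) and Rsad2 (4.04-fold). Sub-cluster 1 (475 nuclei) was higher in the tissue-resident list, 2.0-fold (1.55 to 2.59) on Mrc1 (2.79-fold) and Maf (1.56-fold). Its leading genes, Tmem150b, Dip2a, Nav1, Dgcr8, Was and Bak1, were 4.72-fold to 7.87-fold, the last for Tmem150b with an interval of 2.45 to 40.3. Sub-cluster 4 had 5 nuclei, all from cluster 3, with a median of 540 UMIs, and 3 lists (NF-kB, ATF4, immediate early and heat shock) passed the limit. Hdc led, with 32 UMIs there and 1 in the other macrophage-like nuclei on the counts not used to cluster. In all, 13 of 84 pairs of list and sub-cluster were called. With another seed of the clustering and count split the number was 6, with resolution 0.3 it was 5, and with well 1 alone, an alternative chosen after seeing the data, it was 7. Counted as called in any sub-cluster, which need not hold the same nuclei, the NF-kB and immediate early lists were called in 20 of 20 alternatives, the ATF4 list in 19, the tissue-resident in 18, the TAM in 17, FLCN-Rag-TFE and hypoxia in 15 each, transport in 12, interferon in 8 and MHC class II in 7. Of lists not called in the main analysis, S phase and G2 and M phase were called in 11 each, lipid-associated in 6, genes selected against in 4, alternative activation in 3 and ribosome biogenesis in 2.

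With cluster 2 added, a set of 1243 nuclei chosen after seeing the data, a sub-cluster with resident macrophage genes and another with Gpnmb separated. Sub-cluster 3 of this wider set (277 nuclei, 33 from well 1 and 244 from well 2) had 15.4-fold (95% interval 13.7 to 17.3) the tissue-resident list of the other nuclei, with 5 of 5 measured members higher, the mannose receptor gene Mrc1 at 22.7-fold and the scavenger receptor gene Cd163 at 81.6-fold (26.8 to 405) among them. Within wells the ratio was 12.9 in well 1 and 9.81 in well 2. It was led by Ednrb (351-fold), Retnla (263-fold), Slc28a2 (167-fold), Bank1 (156-fold), Nhsl2 (145-fold) and F13a1 (137-fold), and the first 5 of these had 1 UMI each in the other nuclei, which puts their lower limits at 24.7-fold to 61.6-fold. For F13a1, the coagulation factor XIII gene, which is also on the monocyte marker list, the interval was 89.9 to 220. Of the 277 nuclei, 257 came from cluster 2, where monocyte markers summed to 2682 CPM, against 57.2 CPM in macrophage-like nuclei. The list of genes selected against was 4.16-fold (3.44 to 5.03) there, on Itgam alone, and 3.27 within well 1 and 2.69 within well 2. The ATF4 list was 1.60-fold (1.43 to 1.80), with 3 of 19 measured members higher and 2 lower, Cebpb at 3.18-fold and Atf4 at 0.588-fold among them. Within well 1 its ratio was 1.57 (1.06 to 2.25) and within well 2 0.888 (0.757 to 1.04), so the wells disagree on it.

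Sub-cluster 4 of the wider set (137 nuclei, 43 from well 1 and 94 from well 2) was led by Gpnmb (158-fold, 95% interval 81.6 to 350), a glycoprotein gene of lipid-laden macrophages, with Pde10a (122-fold, 39.5 to 608), Tmem267 (40.8-fold), the podoplanin gene Pdpn (23.8-fold), Lonrf3 (16.8-fold) and Colec12 (15.7-fold). FLCN-Rag-TFE genes were 2.01-fold (1.88 to 2.14), 1.90 within well 1 and 1.86 within well 2. Of 16 members 4 were higher, Fnip2 (3.73-fold), Lamtor3 (2.18-fold), Flcn (2.15-fold) and Fnip1 (2.06-fold), while Tfeb was 0.573-fold. The TAM list was 2.03-fold (1.87 to 2.21), with Spp1 and Mmp12 at 3.12-fold each beside Gpnmb and with Cx3cr1 at 0.563-fold. Gpnmb, also on the lipid-associated list, made up 214 of the 730 UMIs of the TAM list there, against 9 UMIs in the other nuclei. The ratio without Gpnmb was not computed. Within wells its ratio was 1.96 (1.71 to 2.23) in well 1 and 4.18 (3.60 to 4.86) in well 2. The ATF4 list was 1.99-fold (1.75 to 2.26), with Ddit3 at 4.34-fold, Atf4 at 4.11-fold and Slc7a11 at 3.86-fold, and 1.97 within well 1 and 1.42 within well 2. The lipid-associated list was 1.74-fold (1.66 to 1.83), with 11 of 18 members higher, such as Lgals3 (4.18-fold), the lipid droplet gene Plin2 (4.12-fold) and Cd9 (3.52-fold), and 1.28 within well 1 and 1.78 within well 2. Hypoxia and glycolysis genes were 1.65-fold (1.49 to 1.82), with 10 of 15 members higher, among them Hilpda (14-fold) and Ndrg1 (7.19-fold), and 1.61 within well 1 and 1.68 within well 2. MHC class II genes were at 0.303-fold (0.279 to 0.328), with 8 of 9 members lower, Ciita at 0.0869-fold and Cd74 at 0.263-fold, and 0.436 within well 1 and 0.272 within well 2.

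Sub-clusters 1 and 2 of the wider set were mostly nuclei of well 1. Sub-cluster 2 (328 nuclei, 323 from well 1) again carried the immediate early and heat shock list at 4.20-fold (95% interval 4.05 to 4.36), the NF-kB list at 3.84-fold (3.64 to 4.05) and the MHC class II list at 1.54-fold (1.48 to 1.59). Within well 1 these ratios were 6.88, 4.49 and 1.41, and well 2 had too few of these nuclei for a ratio. It was led by Il1r2, the decoy receptor of interleukin 1 (14.6-fold), Hsph1 (13.6-fold), Grasp (11.5-fold), Slc5a3 (10.7-fold), Mrps6 (10.3-fold) and Arl5c (10.2-fold). Slc5a3 lies within the span of Mrps6 on the same strand of chromosome 16, so their counts may not be separable. Sub-cluster 1 (501 nuclei, 462 from well 1) was led by Lpar3, Lilra5, Strip2, Ifnlr1, Nr6a1os and Gna14, at 4.56-fold to 6.08-fold. S phase genes were 1.79-fold (1.53 to 2.11), with 3 of 14 members higher, alternative activation 1.54-fold (1.48 to 1.61) on Tgfbr1 alone (2.14-fold) with 6 of 13 members lower, and G2 and M phase genes 1.51-fold (1.25 to 1.82), with 3 of 15 members higher and 1 lower. Within well 1 these ratios were 1.5, 1.27 and 1.03, and within well 2, with 39 nuclei in the sub-cluster, 3.45 (2.23 to 5.18), 1.82 (1.57 to 2.11) and 2.64 (1.25 to 5.09). In the wider set 14 of 84 pairs were called.

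**Figure D2:**
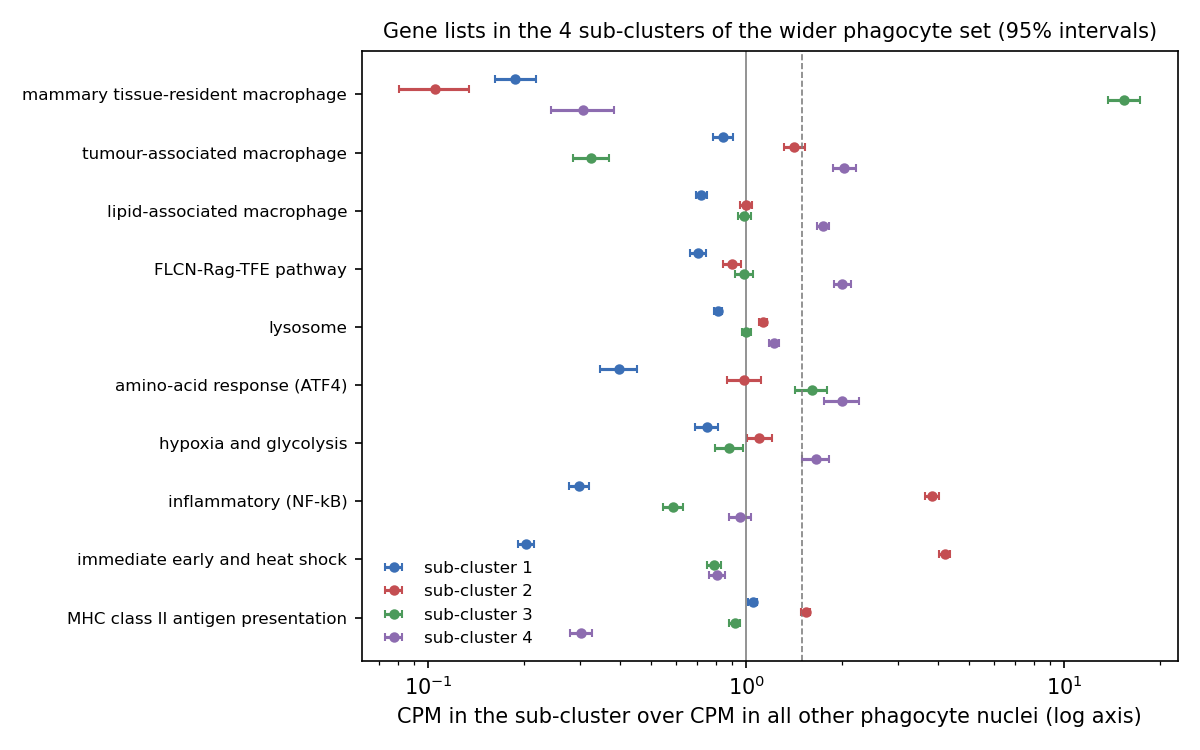
Ratio of the level of 10 gene lists (y axis) in each of the 4 sub-clusters of the wider set of 1243 nuclei to that in its other nuclei (x axis, log scale). Points are ratios of summed CPM, error bars exact 95% intervals of counting error, the solid line 1 and the dashed line the 1.5-fold limit. Resident genes are at 15.4-fold in sub-cluster 3 and FLCN-Rag-TFE genes at 2.01-fold in sub-cluster 4, where MHC class II genes are at 0.303-fold.

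When the 804 macrophage-like nuclei with at least 1000 UMIs were ordered by lysosome level into 3 groups of 268, no list reached the 1.5-fold limit between the highest and the lowest group. The lysosome list itself, on separate counts, differed by only 1.54-fold (95% interval 1.43 to 1.66). A list that followed it as closely would barely reach the limit, so the lack of calls does not show that no list follows lysosome level. Lipid-associated genes came closest at 1.49-fold (1.33 to 1.66), followed by immediate early and heat shock genes at 1.43-fold (1.30 to 1.57) and FLCN-Rag-TFE genes at 1.28-fold (1.10 to 1.5), and phagocytosis genes were at 0.999-fold (0.919 to 1.08). Cell cycle genes went the other way, S phase genes at 0.590-fold (0.360 to 0.953) and G2 and M phase genes at 0.419-fold (0.239 to 0.710). In the wider set S phase genes did not show this, at 0.983-fold (0.683 to 1.41), and G2 and M phase genes were at 0.609-fold (0.398 to 0.920). The list called there was immediate early and heat shock, at 1.58-fold (1.45 to 1.71). The count of 0 higher lists became 1 or 2 in all 11 alternatives run. A single simulation without structure also gave 1 call.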

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

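The tests of sex-linked genes in the clustering, of genotype and of chance reuse of barcodes were chosen after their results had been seen, and those of depth and shared barcode profiles before. Results are taken up here where signal appeared in data that no comparison above uses, above the limit that a count of 0 allows.

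A total of 9 barcode sequences occurred in both wells, against a limit of 3. The copies in well 1 held 56453 to 103328 UMIs and those in well 2 336 to 560, or 0.498% to 0.598% of their partner, and 6 of the 9 well 2 copies were removed by the filter. All 9 well 1 copies lay in clusters 5 and 6. In 9 of 9 pairs the well 2 profile correlated best with its own partner among the 9, though by a small margin (r 0.293 to 0.370 across genes, which are not independent replicates), as reads of well 1 assigned to well 2 would give. Chance reuse of barcodes is argued against by the depth of the well 1 copies, whose median percentile in their well was 99.6. No biological explanation was tested.

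In well 2, 43.7% of phagocyte nuclei with at least 1000 UMIs had a UMI of a Y-linked gene after thinning. A separate draw of the thinning, over all nuclei, gave 49.3% in cluster 2 of well 2, with an Xist UMI in 0.875%. In that draw 0 of 1092 nuclei of all types in well 1 had a Y-linked UMI and 77.8% an Xist UMI. Xist was seen in 80.0% of cluster 1 and 77.4% of cluster 3 of well 1. The wells differed in their phagocyte makeup as well, with a total variation distance over the 4 sub-clusters of the wider set of 0.797. With 1 library per well, how far 2 libraries of 1 kind would differ is not known. Depth does not account for this distance, which was 0.779 with each nucleus thinned to 1000 UMIs, and neither do sex-linked genes in the clustering, with 0.786 when they were left out. The genotype of the tumour-bearing mice cannot be told apart from the sex of the marrow donors or any other property of a library, since 0 wells were mapped to a genotype and each is 1 library. By these UMIs, the phagocyte nuclei of well 2 carried the sex-linked transcripts of male cells and those of well 1 the transcripts of female cells. This rests on 1 library per well. The labels do not state the sex of the marrow donors, and how marrow was assigned to the 2 groups was not tested.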

How the results depend on the processing

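The alternatives chosen after seeing the data are the 2 other rankings of variable genes, the 30-UMI minimum for leading genes, clustering without sex-linked genes, the set with cluster 2, removal of shared barcodes and each well alone; the others were set in advance. No paired analysis was possible because no nucleus maps to a sample and each genotype has 1. For the same reason 7 alternatives fixed in advance on the MYC-PyMT against control-PyMT ratios were not run. The summed level of the genes selected for stayed within its counting interval in 5 of 5 alternatives (1047 to 1061 CPM), and the number of list genes at 10 CPM within 234 to 242 in 19 of 19.

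The share of macrophage-like nuclei, 47.5%, stayed within its interval in 10 of 17 alternatives. It was 54.2% with at least 1000 UMIs, which removes most of the low-UMI cluster, 51.9% at resolution 1.0 and 52.0% with Pearson residuals. It was 68.6% with the 30-UMI minimum and with cluster 2 added, which both take in cluster 2. With well 1 alone it was 60.4% and with well 2 alone 60%. The number of pairs of list and sub-cluster called, 13, stayed within 1.5 times in 15 of 20 alternatives. It was 5 at resolution 0.3, 7 with 1000 variable genes, 6 with another seed, 8 with a 2-fold limit, which is stricter by construction, and 7 with well 1 alone. For the others the cause was not tested.

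The count of lists that passed the 1.5-fold limit with lysosome level was 0. It became 1 when nuclei were thinned to 500 UMIs, when they were not thinned and without the most abundant lysosome member. It was also 1 with Pearson residuals, with the 30-UMI minimum, without sex-linked genes, with cluster 2 and without shared barcodes. It became 2 with the ranking by dispersion, with well 1 alone and with well 2 alone. The cause was not tested. Lipid-associated genes, at 1.49-fold, lie just under the limit. Depth limits these results: 56 of the 860 macrophage-like nuclei had under 1000 UMIs and sub-cluster 4 has 5 nuclei, and in the simulation 44 of 100 genes changed 2-fold were called.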

Other observations

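Of the tests below, those of Y-linked UMIs and of Trps1 in well 2 were chosen after their results had been seen, and those of spread, doublets and Trps1 in well 1 before. A sort for macrophages held 266 nuclei in clusters 5 and 6, with epithelial markers. This leaves out the 292 nuclei of the low-UMI cluster 4, which had epithelial and macrophage markers. Macrophage-like nuclei carried epithelial transcripts too. In macrophage-like nuclei of well 1 thinned to 1000 UMIs, the variance of epithelial-marker UMIs over their mean was 1.27 (1.18 without Trps1). Both lie under the bound of 1.5 set in advance for evenly spread free RNA, but above the 0.902 to 1.13 (0.899 to 1.11 without Trps1) that Poisson counting alone gives, a comparison added after the result was seen. Levels in macrophage-like nuclei of both wells ranged from 4.26% of those in clusters 5 and 6 for Erbb3 to 27.8% for Csn3. This range decides nothing, because free RNA need not have the makeup of clusters 5 and 6. Whether evenly spread free RNA is the source stays open. For the list as a whole in macrophage-like nuclei of well 1, doublets as the main source are argued against. The 5% of these nuclei with most such UMIs held 14.9% of them, where Poisson counting alone gives 13.7%. Trps1 made up most of these UMIs (mean of 2.02 per nucleus, 0.829 without it), and the share was not computed without it. Doublets placed in other clusters, such as cluster 4, are not covered. In well 2 the nuclei of cluster 5 are not explained by free RNA on donor phagocytes. After thinning, 0% of 28 had a Y-linked UMI (upper limit 12.3%), against 43.7% of 357 phagocyte nuclei (38.5 to 49.0), or 49.3% in cluster 2 in a separate draw. In that draw 39.3% of the 28 (21.5 to 59.4) had an Xist UMI. The Xist share was 0.875% in cluster 2 of well 2 and 85.8% in cluster 5 of well 1. Cluster 6 had 0 nuclei in well 2. The test cannot cover the 236 nuclei of clusters 5 and 6 in well 1, where phagocytes had no Y-linked UMI either. How nuclei of clusters 5 and 6 passed the mCherry gate stays open, and no biological explanation was tested.

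Levels over all nuclei of a well mix levels within clusters with the shares of its clusters. Wfdc18, a milk whey protein gene, stood at 926 CPM over the nuclei of well 1 (95% interval 901 to 951) and 102 CPM over those of well 2 (86.1 to 119), and Epcam at 265 CPM against 86.2 CPM. Vcam1 was at 120 CPM in well 1 and 60.0 CPM in well 2, and Itgam at 62.8 CPM against 366 CPM. These are values of 2 single libraries with no replicate.

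Trps1, a transcription factor gene on the epithelial marker list, was seen at a like level in the phagocyte clusters of both wells. It stood at 1184 CPM in cluster 1 and 1151 CPM in cluster 3 of well 1 and at 1164 CPM in cluster 2 of well 2. Wfdc18 and Csn3 together were at 556 CPM and 667 CPM in those clusters of well 1 and at 18.0 CPM in cluster 2 of well 2. A hypothesis is that phagocyte nuclei make Trps1 themselves and that its place on an epithelial list misleads here. Free RNA would give nuclei that make none of these genes the ratio of Trps1 to Wfdc18 and Csn3 of its source. Possible sources differ in it: in well 1 it was 2.69 in cluster 5 and 2.56 in cluster 6, with epithelial markers, and 0.206 in the low-UMI cluster 4. The phagocyte clusters of that well lie between, at 2.13 in cluster 1, 2.13 in cluster 2 and 1.73 in cluster 3. The ratio in cluster 1 over that in cluster 3 was 1.23 (1.08 to 1.40), inside the 1.5-fold bound set in advance for free RNA, but Trps1 made by phagocytes of both clusters would give the same, so this test leaves the source open. In well 2 the ratio was 64.6 in cluster 2, above both 5.45 in cluster 5 and 0.553 in cluster 4. It was 11.9 times (7.55 to 18.6) that in cluster 5, which argues against free RNA of the makeup of either cluster as the source of Trps1 in phagocytes of that well. Transcription of Trps1 in TAMs may be the source, as a hypothesis found and tested on the same data.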
